A study of Mus musculus with 15 samples.

How the data were processed

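Total RNA of 15 mouse embryonic stem cell samples, 500 ng each, was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels and the file headers. The samples carried the hairpin shCTR or sh4 and were untreated or had received 1 µM retinoic acid for 72 hours, per the labels, with 4, 4, 4 and 3 arrays in the groups shCTR, sh4, shCTR with retinoic acid and sh4 with retinoic acid. Each deposited scanner file held spot intensities: per the file headers, Feature Extraction 10.7.3.1 had subtracted a spatial background, corrected a trend across the array and replaced values that were not above background by a surrogate, with no scaling between arrays. The mean spot intensity and the median local background intensity of each spot were deposited as well, with marks for spots well above background, saturated, uneven, or far from their copies. The authors also deposited a table of log2 values with 45220 entries per array. How it was made is not given in the sources used here. Its columns share 1 distribution to within 0.00608 log2 units, and normexp background correction with an offset of 50 followed by quantile normalisation of the mean spot signal gave the same values, with a median absolute difference of 3.4e-10. Those log2 values served only as an alternative.

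From the scanner files, the 43020 non-control spots were reduced to 39429 probes. Spots marked as uneven or far from their copies were left out, spots of one probe were averaged, and 117 probes without an unmarked spot on some array were dropped, which left 39312. The processed signal was put on the log2 scale and each array's 75th percentile over non-control probes was subtracted. A probe was kept where it was well above background on at least 3 arrays of at least 1 group. For each of the 31829 gene names on the array the kept probe with the highest mean was used, which gave 25090 genes. Of these, 5097 had several kept probes. Symbols came from a RefSeq table of the assembly GRCm38.p6, used for names only: 26055 probes matched, 13374 kept the name in the files and 3358 symbols changed. Coordinates are those of the files, on mm9. Array depth is the signal over background: no spot was saturated, and 73.8% to 79.4% of probes were well above background. The scanner software rated 3 arrays as needing evaluation (sh4 replicate 1 with retinoic acid, untreated sh4 replicate 3 and untreated shCTR replicate 2), with a median variation between copies of a probe of 8.40% to 8.89%, against 3.31% to 6.46% elsewhere. All 15 arrays were used.

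Differences between groups were tested with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8), in 1 model of the 4 groups over all 15 arrays, so that the groups share 1 estimate of spread. The test is limma's moderated one and is two-sided. Benjamini-Hochberg adjustment ran over all genes within a comparison, and the threshold was an adjusted p of 0.05. There were 5 comparisons: sh4 against shCTR untreated, sh4 against shCTR in retinoic acid, retinoic acid against untreated in each hairpin, and the interaction, which is the second hairpin effect minus the first. Groups, comparisons, lists, named genes and most alternatives were fixed before the data were examined.

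The replicate numbers could pair samples, so correlations of each gene's deviations from its group mean were computed between arrays. Arrays on one slide correlated with r of 0.116 to 0.607 in all 21 pairs of the same slide. Slide and replicate number coincide except for sh4 with retinoic acid, whose replicate 3 sat on slide 2 and replicate 4 on slide 3. Replicate 3 correlated with same-slide arrays at 0.409 to 0.607 and with arrays of its own number at −0.533 to −0.349, and replicate 4 at 0.437 to 0.526 and 0.413 to 0.559. Slide and replicate number were each tried as a block. Slide 4 held no array of sh4 with retinoic acid, so within-slide values of its comparisons come from 3 slides.

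For a gene that was well above background on no array of one group, the fitted change is not a bound, so the fold is given as "at least", with that group set to the lowest signal marked well above background on each array. The adjusted p beside such a fold is that of the fitted change, without this replacement, and does not test the fold. A gene list was tested with camera from limma with a preset correlation of 0.01, for lists with at least 5 measured genes, adjusted over the lists within a comparison, and again with an estimated correlation and with fry. Members past the threshold were counted with adjustment over all genes and over the list alone. The 27 lists were subunits of PRC2 and of PRC1, enzymes of H3K36 methylation, naive and core pluripotency, primed epiblast, retinoic acid direct targets and Hox genes. Others were other developmental transcription factors with bivalent promoters, neural ectoderm, mesoderm and primitive streak, endoderm, trophectoderm, germ cell and methylation-restrained genes, 2-cell-like genes, fibroblast (feeder cell) markers, and endothelial and blood markers. The last were G2 and M phase, cyclin-dependent kinase inhibitors, p53 targets, interferon response, hypoxia and glycolysis, sterol synthesis, unfolded protein and amino acid stress, heat shock proteins, histone genes, mitochondrially encoded genes and imprinted genes.

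The genes named were Phf19, the 6 largest rises and 6 largest falls past the threshold whose arrays did not overlap between groups and were all well above background in the higher group (for the interaction, in at least 1 group and without the overlap condition). They also included up to 3 members past the threshold of each list that was called or had at least 3 such members, and a fixed panel of pluripotency, PRC2, retinoic acid and lineage genes. Clone, predicted and accession names were left out. Some genes that the rule picks are not named here. Response sets were the genes past the threshold and at least 2-fold on the mean of both retinoic acid responses, a choice balanced between the hairpins. Shared controls were handled by dividing the untreated shCTR arrays between the comparisons.

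The fit was tested on data simulated for 25090 genes, of which 200 were changed. Each probe had its real spread within groups, pooled over the 4 groups. Over the 5 comparisons the fit recovered 32.8% to 55.2% of genes changed 1.5-fold, 52.2% to 77.6% of those changed 2-fold and 78.8% to 95.5% of those changed 4-fold. Of these, 0 had the wrong direction, and at most 13 unchanged genes were called. The simulated arrays were independent, without a slide effect, and far fewer genes changed than in the real data. These rates therefore need not hold for the real arrays. Alternatives were quantile normalisation, normexp background correction, the deposited log2 table, no filter and a filter on all 15 arrays, a mean over probes, and slide or replicate number as a block. Further ones were only the groups compared, a variance trend with intensity, array weights, a 2-fold minimum, no fold minimum for the response sets, both other set tests, and each array left out in turn. Leaving out the 3 arrays rated for evaluation was added after the data were seen. For every comparison the arrays were also regrouped in all 35 ways, or in 100 draws for the interaction. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.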

Results

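Gene expression was measured in mouse embryonic stem (ES) cells that carried the short hairpin RNA sh4 or the control hairpin shCTR, either untreated or after 72 hours in 1 µM retinoic acid, a vitamin A derivative that drives ES cells to differentiate. Each of 15 total RNA samples was hybridised alone to a 1-colour Agilent whole-genome array. There were 4 arrays each of untreated shCTR, untreated sh4 and retinoic acid-treated shCTR, and 3 arrays of retinoic acid-treated sh4. The labels do not say which gene sh4 targets; the series title names Phf19, an accessory subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3. The titles call the samples biological replicates and nothing states that they were separate cultures, so p-values measure only the spread between these samples. The number of arrays limits the precision. For the untreated cells the labels give no treatment time. Effects credited below to retinoic acid therefore cannot be told apart from those of 72 hours of culture. The arrays sat on 4 slides, and sh4 with retinoic acid was missing from slide 4. Between 73.8% and 79.4% of probes were well above background, the 75th percentile of the signal lay between 1509 and 1911 intensity units, and no spot was saturated. Over the 25090 genes tested, replicates of one group differed by a root mean square of 0.32 to 0.72 log2 units. Changes are log2 fold changes ± standard error with adjusted p from limma, and a gene "rose", "fell" or "changed" only where adjusted p was under 0.05.

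Phf19 was lower in every sh4 array than in every shCTR array of the same treatment. Relative to each array's 75th percentile, its log2 level was −0.93, −0.98, −0.70 and −0.69 in untreated shCTR and −2.61, −2.54, −2.51 and −2.54 in untreated sh4. After retinoic acid it was −3.01, −3.06, −3.05 and −2.80 in shCTR and −3.90, −3.97 and −3.71 in sh4. In untreated cells sh4 thus kept 30.2% of the control level (log2 fold change −1.73 ± 0.09, adjusted p = 7.4e-09; within slides −1.68, −1.56, −1.81 and −1.85). In retinoic acid it kept 54.4% (−0.88 ± 0.09, adjusted p = 2.0e-05; within slides −0.89, −0.91 and −0.66). After retinoic acid Phf19 stood at 22.4% of its untreated level in shCTR (−2.16 ± 0.09, adjusted p = 7.3e-11) and at 40.3% in sh4 (−1.31 ± 0.09, adjusted p = 3.7e-08). Treated control cells therefore held less Phf19 RNA than untreated sh4 cells, by −0.43 ± 0.09 (adjusted p = 6.4e-04). The hairpin effect differed between treatments, by 0.85 ± 0.13 (adjusted p = 3.6e-04). Phf19 was read by 1 probe, on the minus strand of chromosome 2 from 34749588 to 34749646 in mm9, and its signal was well above background on all 15 arrays.

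**Figure D1:**
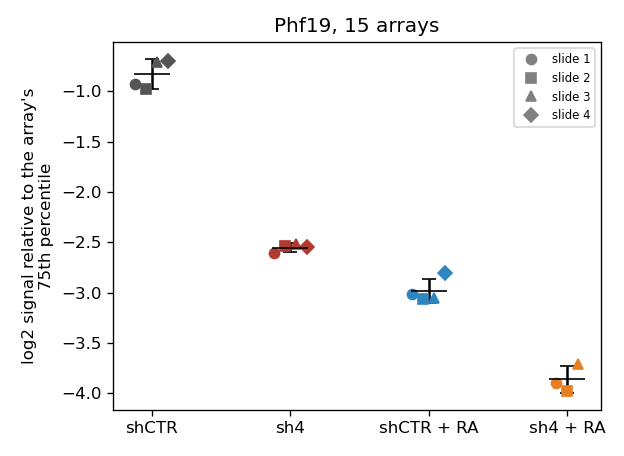
Phf19 log2 signal relative to the 75th percentile of the same array (vertical axis) for each array of the 4 groups (horizontal axis); symbols give the slide and bars the mean and SD. Untreated shCTR arrays lie between −0.98 and −0.69, and retinoic acid-treated sh4 arrays between −3.97 and −3.71.

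Retinoic acid set the arrays apart most. The first principal component held 72.0% of the variance and parted treated from untreated arrays. The second, with 8.77%, parted slides 1 and 2 from slides 3 and 4 within every group. The third, with 7.44%, parted sh4 from shCTR under both treatments, and the fourth, with 3.37%, parted the hairpins in opposite directions without and with retinoic acid. With the slide as a block, 9049, 7053, 17677, 16992 and 6902 genes passed the threshold for the hairpin in untreated cells, the hairpin in retinoic acid, retinoic acid in shCTR, retinoic acid in sh4, and the interaction. With the replicate number as a block the counts were 8141, 6283, 16715, 15595 and 5990. Every gene named below that passed its test, 48, 53, 56, 52 and 40 in these 5 comparisons, had the same sign within each slide and passed with the slide as a block. Except for the interaction, the largest rises and falls were chosen with arrays that do not overlap. That choice alone fixes their sign within slides.

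**Figure D2:**
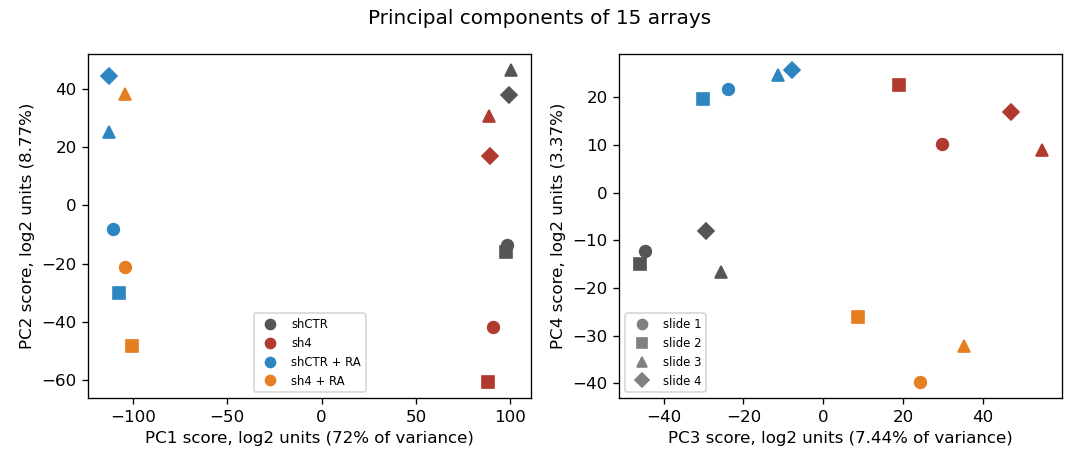
Scores of the 15 arrays on principal components 1 and 2 (left) and 3 and 4 (right), in log2 units; colour gives the group and symbol the slide. The first component, with 72.0% of the variance, follows retinoic acid, the second follows the slides, and the third follows the hairpin.

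The comparison of sh4 with shCTR in untreated cells asks which genes depend on the hairpin while the cells are kept as ES cells. Among the largest rises, Cdx2, the transcription factor that sets the trophectoderm lineage, rose by 4.16 ± 0.14 (adjusted p = 2.7e-10). Krt7 and Krt18, keratins of simple epithelia, rose by 4.02 ± 0.11 and 3.91 ± 0.13, and Thbs1, the matrix protein thrombospondin 1, by 4.39 ± 0.12. The guanylate-binding proteins Gbp2 and Gbp2b rose by 4.69 ± 0.13 and 4.65 ± 0.27. Gbp3 was at least 34.0-fold higher (adjusted p = 2.6e-09) and Oasl2, an antiviral protein of the oligoadenylate synthetase family, at least 15.4-fold (adjusted p = 1.3e-08). "At least" marks a gene that was well above background on no array of one group, and its fold is set against the lowest level that was well above background on each array. The adjusted p beside it belongs to the fitted change, which uses values below background, and not to that fold. Skeletal muscle actin Acta1 rose by 4.35 ± 0.20. The largest falls were in Nostrin, which binds endothelial nitric oxide synthase (−3.12 ± 0.10, adjusted p = 1.1e-10), the myosin gene Myo1f (−2.76 ± 0.37) and the water channel Aqp8 (−2.74 ± 0.22). Timd2, a ferritin receptor, fell at least 4.30-fold, Rufy4 at least 5.08-fold and Fam170a at least 1.90-fold, with adjusted p of 1.8e-06, 3.9e-08 and 4.1e-09. In all, 7149 of 25090 genes changed, 3608 up and 3541 down, of which 778 and 860 changed at least 2-fold. With a normexp background correction, which shrinks differences at low signal, 4643 changed, and more fell (2593) than rose (2050). With quantile normalisation 3118 rose and 3383 fell.

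Of the 27 gene lists, camera called 8 in untreated cells. With an estimated correlation 5 held, and with the slide as a block as well 5 held, where primed epiblast passed and the p53 targets failed (adjusted p = 0.018 and 0.13). The trophectoderm list had 13 of 20 measured members up and 1 down, the same adjusted over the list alone (median 0.89, or 0.86 with 1 gene at its bound, adjusted p = 1.3e-09; within slides 0.87 to 1.18). Besides Cdx2, the placental transcription factor Hand1 rose by 3.03 ± 0.11. In the primed epiblast list 11 of 18 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.62, adjusted p = 6.0e-07), and the call was lost with an estimated correlation (adjusted p = 0.059). Cldn6, a tight junction protein, rose by 3.37 ± 0.08 and the growth factor Fgf5, a marker of the epiblast after implantation, by 2.61 ± 0.08. Imprinted genes, expressed from 1 parental copy, rose for 15 of 25 with 1 fall, or 16 and 1 adjusted over the list alone (median 0.55, adjusted p = 6.2e-08), among them the growth factor Igf2 (1.71), Peg3 (1.70) and Peg10 (1.67). The p53 targets rose for 16 of 23 and fell for 2, the same adjusted over the list alone (median 0.39, adjusted p = 8.9e-06). Perp, a desmosomal protein, rose by 1.70, the antiproliferative Btg2 by 1.04 and the kinase Plk2 by 0.99.

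The endoderm list had 14 of 30 down and 5 up, or 15 and 6 adjusted over the list alone (median −0.46, or −0.37 with 2 genes at their bound and −0.25 with the normexp correction, adjusted p = 2.6e-05). Its call was lost with an estimated correlation (adjusted p = 0.18). Those that fell included 3 markers of primitive endoderm, the growth factor receptor Pdgfra (−2.43 ± 0.05) and the transcription factors Sox7 (−2.05) and Gata6 (−1.91). Among the members that rose was Krt19, a keratin of simple epithelia (2.56 ± 0.18). No 2-cell-like gene rose and 13 of 17 fell, or 14 adjusted over the list alone (median −1.20, or −1.16 with 1 gene at its bound and −0.78 with the normexp correction, adjusted p = 1.1e-10). Tdpoz3 (−2.11), Tcstv3 (−1.70) and Tdpoz4 (−1.60) belong to families transcribed in the 2-cell embryo. Germ cell genes fell for 15 of 28 and rose for 4, or 17 and 4 adjusted over the list alone (median −0.40, adjusted p = 1.8e-03). Stra8, the gatekeeper of meiosis, fell by 2.11, while the homeobox genes Rhox6 and Rhox9 rose by 1.77 and 1.49. Histone genes fell for 8 of 22 with no rise, the same adjusted over the list alone (median −0.20, adjusted p = 2.9e-03), for example H3c1 (−0.98) and H3c8 (−0.77). That call too was lost with an estimated correlation (adjusted p = 0.15). H2aw, at −0.73, passed with adjusted p = 0.034 and failed without any one of sh4 replicates 2, 3 and 4 and shCTR replicates 1 and 2 (adjusted p = 0.071 to 0.10).

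The other 19 lists were not called in untreated cells. Of the 12 PRC2 subunits, 1 rose and 3 fell, the same adjusted over the list alone (median −0.16, adjusted p = 0.088). Ezh1, the other methyltransferase, chosen here after its value was seen, rose by 0.33 ± 0.06. Besides Phf19 the falls were in Suz12, a core subunit (−0.56 ± 0.07), and the accessory subunit Epop (−0.74 ± 0.18). Ezh2, the main methyltransferase, measured −0.10 ± 0.06, Eed −0.18 ± 0.07 and Mtf2, a paralogue of Phf19, −0.14 ± 0.08. Of 30 naive and core pluripotency genes, 9 fell and 3 rose, or 9 and 4 adjusted over the list alone (adjusted p = 0.22). The naive factors Tbx3 and Klf4 fell (−1.15 and −1.05), while Dppa3 of the same list, which guards maternal methylation in the egg, rose by 3.01 ± 0.08. Pou5f1, the gene of Oct4, measured −0.17 ± 0.20 and Sox2 −0.17 ± 0.11, and Nanog measured −0.47 ± 0.24 with an adjusted p of 0.18. Zfp42, a marker of naive ES cells, fell by 0.47 at an adjusted p of 0.034, which rose past the threshold without any one untreated array (0.051 to 0.083). Without sh4 replicate 4 of the retinoic acid group, which enters through the shared estimate of spread, the naive list was called (adjusted p = 0.038, against 0.66 with all arrays and an estimated correlation) and Nanog fell by 0.47 (adjusted p = 1.5e-03). With only the untreated arrays in the fit, the naive list and Nanog passed too (adjusted p = 0.021 by camera and 3.5e-03 by limma). Hox genes had 7 of 37 up and 10 down (median −0.14, or −0.04 under another scaling, adjusted p = 0.22). They were called as lower with the normexp correction (−0.18, adjusted p = 0.019) and among genes well above background on all 15 arrays (−0.33, adjusted p = 0.029), but not with an estimated correlation (adjusted p = 0.52). Retinoic acid direct targets had 10 of 29 up and 11 down (adjusted p = 0.91). Other bivalent transcription factors had 17 of 90 up and 22 down, with a median of 0.07, or 0.04 with 1 gene at its bound, and a test that pointed down (adjusted p = 0.47). The interferon list divided, 7 of 25 up and 9 down, with a median of −0.05 and a test that pointed up (adjusted p = 0.97); the chemokine Cxcl10 rose by 2.98 ± 0.12. Among fibroblast markers 11 of 23 rose and 7 fell (median 0.11, or 0.03 with 3 genes at their bound; adjusted p = 0.33). Acta2, smooth muscle actin, rose by 2.96, the matrix proteoglycan Dcn was at least 2.62-fold higher (adjusted p = 1.2e-07), and the collagen Col3a1 at least 1.02-fold (adjusted p = 7.8e-08). With the normexp correction the sign of Col3a1 turned (−0.07) and Dcn lost its call. Adjusted over the list alone the counts up and down were 7 and 10 for Hox genes, 11 and 11 for retinoic acid direct targets and 18 and 25 for bivalent factors. For the last lists they were 8 and 9 for the interferon list and 11 and 7 for fibroblast markers.

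For the remaining lists, not called in untreated cells, counts up and down over all genes were 4 and 2 of 21 PRC1 subunits (adjusted p = 0.62), 4 and 1 of 15 enzymes of H3K36 methylation (adjusted p = 0.21), 11 and 5 of 30 neural ectoderm genes (adjusted p = 0.12, or 0.037 averaged over probes and 0.36 with an estimated correlation), and 5 and 9 of 27 mesoderm genes (adjusted p = 0.67). They were 3 and 8 of 20 endothelial and blood markers (adjusted p = 0.24), 0 and 2 of 26 genes of G2 and M phase (adjusted p = 0.22), and 1 and 2 of 8 cyclin-dependent kinase inhibitors (adjusted p = 0.33). Hypoxia and glycolysis genes had 3 and 9 of 29 (adjusted p = 0.12), and sterol synthesis genes 8 and 4 of 23 (adjusted p = 0.33). For 26 genes of unfolded protein and amino acid stress they were 3 and 10 (adjusted p = 0.069, or 0.047 with the slide as a block and 0.27 with an estimated correlation besides). Heat shock proteins had 0 and 1 of 15 (adjusted p = 0.88) and mitochondrially encoded genes 5 and 0 of 11 (adjusted p = 0.16). Adjusted over the list alone the same lists, in the same order, had 5 and 2, 4 and 1, 12 and 5, 5 and 9, 3 and 8, 0 and 0, 1 and 3, 3 and 9, 8 and 4, 4 and 10, 0 and 1, and 5 and 0.

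**Figure D3:**
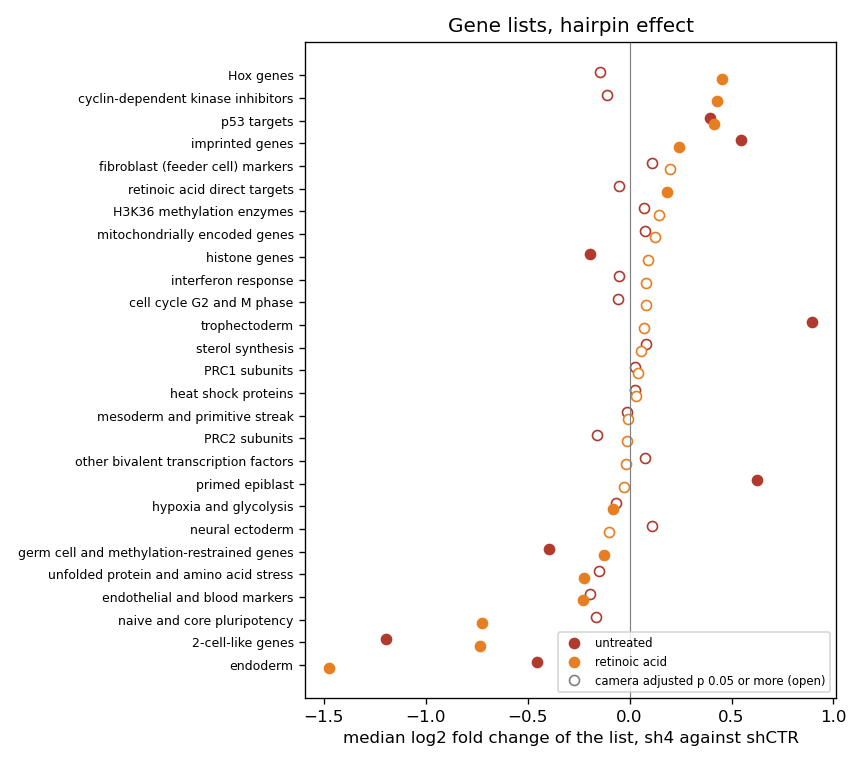
Median log2 fold change of sh4 against shCTR (horizontal axis) for each of the 27 gene lists (vertical axis), untreated and in retinoic acid; filled points mark lists called by camera, open points those not called. The endoderm list has the lowest median in retinoic acid (−1.47) and the trophectoderm list the highest in untreated cells (0.89).

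In retinoic acid, the comparison of sh4 with shCTR asks which genes depend on the hairpin once the cells differentiate. Endoderm genes were lower in sh4. Hnf4a, a transcription factor of visceral endoderm and liver, fell by 3.51 ± 0.11 (adjusted p = 5.6e-10). Ttr, a carrier of thyroid hormone, fell by 3.41 ± 0.15, and the endocytic receptor Cubn fell by 2.99 ± 0.13; both are also active in visceral endoderm. Fabp1, a fatty acid binding protein of liver and gut, was at least 11.4-fold lower (adjusted p = 9.1e-07), Prame at least 7.17-fold (adjusted p = 1.5e-05) and the kinase Ptk6 at least 3.95-fold (adjusted p = 1.8e-07). Ugt2b34, a glucuronosyltransferase, fell by 3.72 ± 0.42 and Nepn, nephrocan, fell by 3.64 ± 0.38. Among the genes that rose most were Macc1 (3.52 ± 0.17, adjusted p = 1.8e-08), the protease Pappa2 (2.53 ± 0.10), Prom2 (2.45 ± 0.20) and the membrane protease Tmprss4 (2.37 ± 0.21). Cldn8, a tight junction protein, was at least 4.47-fold higher (adjusted p = 1.5e-06) and Spink8, a protease inhibitor, at least 2.89-fold (adjusted p = 2.3e-06). With the normexp correction 3389 genes changed. Cldn8 (0.56), Spink8 (0.50), Ptk6 (−0.46), Asz1 (−0.27) and Suz12 (−0.31) then lost their calls, at the log2 values given. In all, 5308 genes changed, 2725 up and 2583 down, and at least 2-fold 129 rose and 724 fell.

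Camera called 12 lists in retinoic acid, of which 4 held with an estimated correlation: endoderm, 2-cell-like, endothelial and blood, and p53. With the slide as a block as well, endoderm and 2-cell-like held and the other 2 did not (adjusted p = 0.094 each). The endoderm list had 25 of 30 members down and none up, or 26 down adjusted over the list alone (median −1.47, adjusted p = 7.9e-31; within slides −1.47 to −1.42). The transcription factors Sox7 (−2.51), Gata4 (−2.47) and Gata6 (−1.32) were among them. The 2-cell-like list fell for 12 of 17 with no rise, or 13 adjusted over the list alone (median −0.74, adjusted p = 3.5e-10), with Pramel7 at −2.70, Pramel6 at −1.34 and Calcoco2 at −0.99. Endothelial and blood markers fell for 6 of 20 with no rise, or 7 adjusted over the list alone (median −0.23, adjusted p = 2.5e-04; −0.09 with the normexp correction and −0.10 without sh4 replicate 4). Among these were the endothelial adhesion molecules Cdh5 (−2.47) and Esam (−2.16) and the blood stem cell factor Runx1 (−1.75). The p53 targets rose for 16 of 23 and fell for 1, or 17 and 2 adjusted over the list alone (median 0.41, adjusted p = 7.3e-08). Perp rose by 1.38 and Btg2 by 0.84. Rrm2b, at 0.75 with an adjusted p of 0.044, failed without any one of 8 arrays (0.054 to 0.17).

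The other 8 calls in retinoic acid were lost with an estimated correlation. Naive and core pluripotency genes fell for 18 of 30 and rose for 3, or 21 and 4 adjusted over the list alone (median −0.73, adjusted p = 1.7e-08; 0.11 with an estimated correlation). Pou5f1 (−1.80 ± 0.22), Nanog (−1.13 ± 0.26), Tcl1 (−2.69), Fbxo15 (−1.22) and Zfp42 (−0.75) fell. Nanog and Zfp42 lost their calls with only the treated arrays in the fit. In contrast Sox2, which also marks neural progenitors, rose by 0.84 ± 0.12. Hox genes, the factors of anterior-posterior identity, rose for 14 of 37 and fell for 1, or 19 and 3 adjusted over the list alone (median 0.46, adjusted p = 1.2e-04; 0.094 with an estimated correlation). Hoxd4 rose by 1.20 and Hoxd1 by 0.93. Hoxc5, at 0.99 with an adjusted p of 0.034, failed without any one of 6 treated arrays (0.062 to 0.091). Retinoic acid direct targets rose for 10 of 29 and fell for 3, or 14 and 4 adjusted over the list alone (median 0.18, adjusted p = 0.036; 0.32 with an estimated correlation). The retinoic acid carrier Crabp2 rose by 1.04, while the receptor Rarb measured −0.05 ± 0.09 and Cyp26a1, which degrades retinoic acid, −0.06 ± 0.13. Cyclin-dependent kinase inhibitors rose for 4 of 8 with no fall, the same adjusted over the list alone (median 0.43, adjusted p = 0.036; 0.097 with an estimated correlation), for example Cdkn1a (0.73), Cdkn2a (0.55) and Cdkn1c (0.55). Imprinted genes rose for 8 of 25 with no fall, the same adjusted over the list alone (median 0.24, adjusted p = 7.6e-04; 0.097 with an estimated correlation), with Nnat at 0.86, Zdbf2 at 0.74 and Peg10 at 0.72.

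Unfolded protein and amino acid stress genes fell in retinoic acid for 10 of 26 and rose for 2, or 12 and 2 adjusted over the list alone (median −0.23, adjusted p = 4.3e-04; 0.094 with an estimated correlation). Among those that fell were Chac1 at −0.73, Creld2 at −0.72 and the stress transcription factor Xbp1 at −0.66. Germ cell genes fell for 7 of 28 and rose for 2, the same adjusted over the list alone (median −0.13, or −0.07 with the normexp correction, adjusted p = 0.036; 0.11 with an estimated correlation), such as Xlr4a (−1.81), Rhox5 (−1.55) and Asz1 (−1.53). Hypoxia and glycolysis genes fell for 7 of 29 and rose for 1, or 8 and 1 adjusted over the list alone, including Ndrg1 (−0.64), P4ha2 (−0.64) and Pfkl (−0.63). That list's median was −0.08 with an adjusted p of 0.024, against 0.42 with an estimated correlation and 0.087 with the slide as a block. Leaving out 1 array ended some of these calls: the retinoic acid targets without sh4 replicate 4 (adjusted p = 0.14) or shCTR replicate 1 or 2 (0.058 and 0.079), and the kinase inhibitors without shCTR replicate 2 (0.061). The same held for the germ cell genes without sh4 replicate 1 (0.082, median −0.06) or shCTR replicate 2 (0.074, median −0.05), and for the hypoxia list without sh4 replicate 3 (0.12) or shCTR replicate 4 (0.073). With the replicate number as a block the calls on the retinoic acid targets and the kinase inhibitors ended as well (0.070 and 0.062). Among genes well above background on all 15 arrays those 2 ended too (0.10 and 0.056), with that on germ cell genes (0.060), and the retinoic acid targets also failed with the normexp correction (0.053). Among PRC2 subunits only Phf19 and Suz12 passed; Suz12 fell by 0.39 ± 0.08, while Ezh2 measured 0.11 ± 0.06, Eed −0.08 ± 0.08 and Mtf2 0.01 ± 0.08. Trophectoderm genes, with 8 of 20 up and 6 down, and primed epiblast genes, with 3 of 18 up and 5 down, were not called (adjusted p = 0.93 and 0.30). Histone genes, with 6 of 22 up and 5 down, were not called either (adjusted p = 0.61). Adjusted over the list alone these counts were the same.

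In control cells, the comparison of treated with untreated shCTR describes the response to retinoic acid itself. The lists of naive and core pluripotency genes and PRC2 subunits fell. Those of Hox genes, retinoic acid direct targets, endoderm, trophectoderm and fibroblast markers rose. Of the retinoic acid-degrading enzymes, Cyp26b1 rose by 9.91 ± 0.14 and Cyp26a1 by 9.35 ± 0.12 (adjusted p = 2.6e-15), and the receptor Rarb rose by 6.24 ± 0.09. Hoxb1 was at least 383-fold higher, Hoxb5 at least 298-fold and Hoxa5 at least 203-fold (adjusted p = 7.9e-16, 1.0e-10 and 3.8e-12). The largest rises also took in Arg1, arginase 1, at least 443-fold, cardiac actin Actc1 at least 326-fold, Dcn at least 285-fold, Ttr at least 194-fold and Plat, tissue plasminogen activator, at least 179.8-fold. Their adjusted p were 9.6e-13, 1.4e-14, 1.6e-13, 5.9e-15 and 4.9e-10. The pluripotency factor Foxd3 was at least 250.1-fold lower (adjusted p = 9.6e-09). Inhbb, an activin subunit, fell by 7.08 ± 0.28 and the growth factor Fgf4 fell by 6.91 ± 0.47. Olfr985, Spry4 and Nkx6-3 fell (−7.70, −7.53 and −7.57), with 2, 2 and 1 of 4 treated arrays well above background. In all, 15641 genes changed, 7252 up and 8389 down, of which 4044 and 2919 changed at least 2-fold; the median of all genes was −0.12. With the normexp correction the split was 5271 up and 9292 down, and the median moved by −0.11.

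Of the 13 lists called in shCTR, 11 held with an estimated correlation. With the slide as a block as well 5 held, namely Hox, retinoic acid direct targets, trophectoderm, fibroblast, and G2 and M phase; PRC2, pluripotency and endoderm were then at adjusted p = 0.066, 0.098 and 0.061. Hox genes rose for 31 of 37 and fell for 1 (median 4.04, or 3.44 with 7 genes at their bound and 2.09 with the normexp correction, adjusted p = 4.7e-13). Retinoic acid direct targets rose for 23 of 29 and fell for 4 (median 3.96, adjusted p = 4.2e-10). Endoderm genes rose for 26 of 30 and fell for 2 (median 3.60, adjusted p = 2.3e-12), for example Cubn (7.32), Foxa2 (5.88) and Gata6 (4.75). Trophectoderm genes rose for 15 of 20 and fell for 3 (median 2.65, adjusted p = 4.5e-06). They include Plac1 at 8.11 and the keratins Krt8 and Krt18 at 5.91 and 5.86. Fibroblast markers rose for 20 of 23 and fell for 2 (median 3.74, or 3.00 with 5 genes at their bound and 1.86 with the normexp correction, adjusted p = 1.1e-08), among them Acta2 at 8.21. Naive and core pluripotency genes fell for 28 of 30 and rose for 1 (median −3.18, adjusted p = 3.0e-11), with Nr0b1 at −6.72, Esrrb at −6.24, Sox2 at −5.55, Nanog at −5.06, Zfp42 at −3.97 and Pou5f1 at −3.13. The PRC2 list fell for 10 of 12 and rose for 2 (median −1.35, adjusted p = 1.1e-03). Besides Phf19, the accessory subunits Aebp2 (−1.92), Jarid2 (−1.81) and Mtf2 (−1.76) fell, and so did the core subunits Eed (−1.59), Suz12 (−1.29) and Ezh2 (−0.87). Adjusted over the list alone, the counts up and down of these 7 lists were 31 and 1, 23 and 4, 26 and 3, 16 and 3, 20 and 2, 1 and 29, and 2 and 10.

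Also in shCTR, bivalent transcription factors rose for 49 of 90 and fell for 18 (median 0.79, or 0.26 with the normexp correction, adjusted p = 6.9e-05; 0.0496 with an estimated correlation). Tbx2 rose by 6.30 and the neural factor Pax6 by 0.78 ± 0.13, while Pou4f2 fell by 6.08 and Sox1, another neural factor, fell by 2.51 ± 0.15. The 2-cell-like list rose for 12 of 17 and fell for 3 (median 2.23, adjusted p = 3.6e-04), with Tdpoz1 at 4.31 and Tdpoz4 at 3.57. Imprinted genes rose for 17 of 25 and fell for 5 (median 1.44, adjusted p = 1.3e-04), with Peg3 at 5.42, Dlk1 at 5.30 and H19 at 5.05. Genes of G2 and M phase fell for 19 of 26 with no rise (median −0.51, adjusted p = 1.0e-03), such as Nusap1 (−1.01), Bub1 (−0.82) and Ccnb1 (−0.77). This call was lost with quantile normalisation and with the deposited log2 table, where the median shrank to −0.22 in each. Cyclin-dependent kinase inhibitors rose for 7 of 8 and fell for 1 (median 0.82, adjusted p = 0.039), with Cdkn2b at 3.36 and Cdkn2c at 1.69. The p53 targets rose for 14 of 23 and fell for 5 (median 0.48, or 0.25 with the normexp correction, adjusted p = 0.029), with the death receptor Fas at 3.55 and Plk2 at 1.68. These last 2 calls were lost with an estimated correlation (adjusted p = 0.073 and 0.16), and that on p53 also averaged over probes (0.077). Adjusted over the list alone the counts of the 6 lists were unchanged. The interferon list was not called, with 13 of 25 up and 11 down (adjusted p = 0.23), though Cxcl10 rose by 8.79 ± 0.12. The list's median of 0.51 turned to −0.03 with the normexp correction, and with it Pax6 lost its call. Neural ectoderm genes, 9 of 30 up and 11 down, the same adjusted over the list alone, were not called either (adjusted p = 0.85), and Stmn2 among them fell by 5.06.

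Under the hairpin sh4, the comparison of treated with untreated cells describes the same response in cells that started with less Phf19 RNA. The lists of Hox genes and retinoic acid direct targets rose and that of naive and core pluripotency genes fell, as in control cells. Hoxb1 rose at least 562-fold, Arg1 at least 537-fold, Hoxb5 at least 453-fold and Hoxa5 at least 277-fold (adjusted p = 2.2e-15, 3.4e-12, 9.5e-11 and 1.8e-11). Hoxb2 rose by 9.83 ± 0.12, Cyp26b1 by 9.66 ± 0.15, Cyp26a1 by 8.14 ± 0.13, Dcn by 7.41 ± 0.22, and Rarb by 6.96 ± 0.09. Spry4, an inhibitor of growth factor signalling, fell at least 137-fold (adjusted p = 6.7e-07), Tdh, the threonine dehydrogenase of mouse ES cells, fell by 6.93 ± 0.41, and the epiblast factor Otx2 fell by 6.78 ± 0.10. Fgf4 fell by 7.44, and Olfr985 and Foxd3, well above background on 1 of 3 treated arrays each, measured −8.13 and −7.36. In all, 14688 genes changed, 6775 up and 7913 down, of which 3624 and 2766 changed at least 2-fold; the median of all genes was −0.12. Across genes, which are not independent replicates, the responses of sh4 and shCTR correlated with r = 0.903 and rho = 0.857 (within slides r = 0.862, 0.853 and 0.855). Of 12867 genes that changed in both, 12532 had the same sign and 335 opposite signs.

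Camera called 15 lists in sh4 and 9 held with an estimated correlation. With the slide as a block as well 4 held, namely Hox, retinoic acid direct targets, fibroblast and kinase inhibitors, and pluripotency and endoderm both had adjusted p of about 0.070. Hox genes rose for 32 of 37 with no fall, or 33 adjusted over the list alone (median 4.59, or 2.98 with the normexp correction, adjusted p = 1.7e-16). Retinoic acid direct targets rose for 22 of 29 and fell for 3 (median 4.00, adjusted p = 1.6e-11). Endoderm genes rose for 22 of 30 with 3 falls (median 2.62, or 1.45 with the deposited log2 table, adjusted p = 8.0e-09). Foxa2 rose by 6.18, Gata6 by 5.34 and Ttr at least 18.2-fold (adjusted p = 1.1e-12). Fibroblast markers rose for 21 of 23 with 2 falls (median 2.98, or 2.88 with 2 genes at their bound, adjusted p = 9.4e-10), with Acta2 at 5.77. The 2-cell-like list rose for 12 of 17 and fell for 4 (median 2.70, or 2.48 with 1 gene at its bound, adjusted p = 1.8e-04), with Tdpoz3 at 4.49. Kinase inhibitors rose for 7 of 8 with no fall (median 1.21, adjusted p = 1.2e-03), with Cdkn2b at 3.58 and Cdkn2c at 2.80. Naive and core pluripotency genes fell for 29 of 30 and rose for 1 (median −3.85, adjusted p = 1.8e-13), with Esrrb at −6.84, Nr0b1 at −6.76, Nanog at −5.72, Pou5f1 at −4.77, Sox2 at −4.54 and Zfp42 at −4.25. PRC2 subunits fell for 10 of 12 and rose for 2 (median −1.15, adjusted p = 1.5e-03). Those that fell were led by Jarid2 at −1.77, Aebp2 at −1.61, Mtf2 at −1.60, Eed at −1.49, Suz12 at −1.11 and Ezh2 at −0.66. Genes of G2 and M phase fell for 18 of 26 with 1 rise (median −0.33, adjusted p = 7.3e-03), for example Ccnb1 (−0.82) and Top2a (−0.76). That call was lost with quantile normalisation (median −0.13) and with the deposited log2 table (median −0.06). Adjusted over the list alone the counts of these 8 lists were unchanged.

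For 6 lists the call in sh4 was lost with an estimated correlation. Bivalent transcription factors rose for 50 of 90 and fell for 19, or 50 and 20 adjusted over the list alone (median 0.70, or 0.64 with 5 genes at their bound and 0.32 with the normexp correction, adjusted p = 8.2e-05; 0.055 with an estimated correlation). Tbx2 rose by 7.39, Pou4f2 fell by 6.42, Sox1 fell by 2.16, and Pax6 measured 0.05 ± 0.14. Imprinted genes rose for 15 of 25 and fell for 4, or 15 and 7 adjusted over the list alone (median 1.24, adjusted p = 4.0e-04; 0.058 with an estimated correlation), for example Dlk1 (4.74) and Zim1 (4.08). Histone genes rose for 13 of 22 and fell for 2, or 13 and 3 adjusted over the list alone (median 0.54, or 0.52 with 1 gene at its bound, adjusted p = 2.9e-03; 0.10 with an estimated correlation). H2bu2 rose by 2.85 and the linker histone H1f2 by 2.09. The last 3 lists had the same counts adjusted over the list alone. Trophectoderm genes rose for 13 of 20 and fell for 5 (median 1.26, or 0.71 with the normexp correction, adjusted p = 4.7e-03; 0.12 with an estimated correlation). Plac1 rose by 4.40, Esx1 by 3.93 and Krt7 by 2.79. The p53 targets rose for 12 of 23 and fell for 4 (median 0.49, adjusted p = 9.7e-03; 0.12 with an estimated correlation), with Fas at 3.03. Interferon genes rose for 15 of 25 and fell for 6 (median 0.60, or 0.20 with the normexp correction, adjusted p = 0.041; 0.25 with an estimated correlation), with Cxcl10 at 4.90 and Usp18 at 4.14. That call ended in 7 settings, 2 of them without a single array (sh4 replicate 4 with retinoic acid, 0.071, and untreated sh4 replicate 1, 0.063). Primed epiblast genes, 5 of 18 up and 10 down, were not called (median −0.71, adjusted p = 0.075) but passed in 5 other settings, among them the normexp correction (0.024), and not with an estimated correlation (adjusted p = 0.45).

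The interaction asks directly whether the response to retinoic acid differed between sh4 and shCTR. Trophectoderm and primed epiblast genes were raised less, or lowered more, by retinoic acid in sh4. Their median hairpin effects were 0.89 and 0.62 untreated. In retinoic acid they were 0.07 and −0.03, and neither list was called (camera adjusted p = 0.93 and 0.30). For these lists the interaction thus goes mostly with higher levels in untreated sh4, not with lower ones after treatment. The difference between the responses was −4.71 ± 0.21 for Cdx2, −3.98 ± 0.19 for Krt18 and −3.71 ± 0.12 for Plac1 (adjusted p at most 1.7e-08). Among the most negative values, −5.51 to −5.33, were those of the vitamin C transporter Slc23a1, the chloride channel protein Clic5, the cytokine Il33, the neural factor Olig3 and the lysophospholipase Enpp2. The most positive belonged to Spink8 (3.73 ± 0.39), Adgrd1 (3.42), Nkx6-3 (3.31), Cldn8 (3.19), Kng2 (2.87) and the cadherin Cdh22 (2.82). In groups where a gene was not above background these differences rest on floor values and are no bounds. In all, 5109 genes passed, 2558 up and 2551 down, of which 493 and 985 changed at least 2-fold; with the normexp correction, which moved the median of all genes by 0.10, 3050 passed, 1689 up and 1361 down.

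Camera called 8 lists for the interaction, and the trophectoderm and primed epiblast lists held with an estimated correlation, without and with the slide as a block. Trophectoderm genes had 12 of 20 below and 3 above zero, or 13 and 3 adjusted over the list alone (median −1.01, or −0.67 with the normexp correction, adjusted p = 5.9e-10; within slides −1.30 to −1.01). Primed epiblast genes had 13 of 18 below and none above, the same adjusted over the list alone (median −0.93, adjusted p = 3.6e-10; within slides −0.86 to −0.77). Cldn6 was at −3.03 and Otx2 at −2.03. Endoderm genes had 20 of 30 below and 4 above, or 23 and 5 adjusted over the list alone (median −1.66, adjusted p = 5.8e-10; 0.072 with an estimated correlation). This median was −0.68 with the normexp correction, −0.88 among genes well above background on all 15 arrays, and −1.26, −0.96 and −1.37 within slides. Ttr was at −3.39, Apoa1 at −2.47 and Dab2 at −2.41, but Gata6 at 0.59 ± 0.11. Hox genes had 12 of 37 above and 3 below, or 17 and 3 adjusted over the list alone (median 0.42, or 0.75 among genes well above background on all 15 arrays, adjusted p = 6.1e-04; 0.14 with an estimated correlation), with Hoxb2 at 1.68, Hoxc4 at 1.60 and Hoxd4 at 1.36. Kinase inhibitors had 4 of 8 above and none below, the same adjusted over the list alone (median 0.38, adjusted p = 0.010; 0.072 with an estimated correlation), with Cdkn2c at 1.12, Cdkn1b at 0.84 and Cdkn1a at 0.80. Histone genes had 8 of 22 above and 1 below, the same adjusted over the list alone (median 0.31, adjusted p = 5.9e-03; 0.19 with an estimated correlation). They include H2ax at 0.77 and H1f3 at 1.87, whose adjusted p of 0.021 rose to 0.055 without sh4 replicate 4 of the treated group. Imprinted genes had 10 of 25 below and 2 above, or 12 and 2 adjusted over the list alone (median −0.34, or −0.10 with the normexp correction and −0.21 without sh4 replicate 4 of the treated group, adjusted p = 2.4e-03; 0.16 with an estimated correlation), with Igf2 at −1.69, Peg3 at −1.43 and H19 at −1.39.

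Naive and core pluripotency genes had 11 of 30 below and 2 above in the interaction, the same adjusted over the list alone (median −0.44, adjusted p = 4.2e-03; 0.44 with an estimated correlation). Their median within slides ran from −0.77 to 0.19, and it was −0.24, −0.16 and −0.73 without treated sh4 replicate 1, 3 or 4. Dppa3 was at −3.99 ± 0.12 (adjusted p = 6.3e-10) and the Nodal antagonist Lefty1 at −1.71. Pou5f1 measured −1.63 ± 0.30 and Tcl1 −1.72 ± 0.33, Sox2 1.01 ± 0.16, and Nanog −0.66 ± 0.35 with an adjusted p of 0.25, or −1.12 with 1.7e-04 without sh4 replicate 4 of the treated group. Retinoic acid direct targets were not called, with 13 of 29 above and 7 below, or 14 and 7 adjusted over the list alone (adjusted p = 0.13); Rarb measured 0.73 ± 0.13 and Cyp26a1 −1.22 ± 0.17. The vascular receptor Flt1, an endothelial marker, measured −3.11 ± 0.10 in a list that was not called. With the slide as a block the neural ectoderm and 2-cell-like lists passed as well, each with an adjusted p of 0.041, but not with an estimated correlation (adjusted p = 0.23 and 0.30). With the normexp correction the interaction calls on Cldn8 (0.68), Kng2 (0.66), Apoa1 (−0.63), Igf2 (−0.36) and Peg3 (−0.36) were lost. The same held for Gata6 (0.22), Rarb (0.48), Cyp26a1 (−0.55) and H1f3 (0.41). With the deposited log2 table Gata6 (0.19) and H1f3 (0.15) lost their calls as well, and averaged over probes Rarb and H19 did.

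Genes chosen on the mean of both retinoic acid responses give the size of the response as a whole. Of 3833 induced genes, the median response was 2.01 in shCTR and 1.80 in sh4, and the median interaction was −0.13 (camera p = 4.8e-04, or 0.022 with an estimated correlation; within slides −0.09, −0.14 and −0.19). Among them 967 had a lower and 542 a higher response in sh4, and the slope of the sh4 on the shCTR response was 0.699. For the 2734 repressed genes the medians were −1.59 and −1.50 and the median interaction 0.09 (camera p = 0.022, or 0.17 with an estimated correlation; within slides 0.09, 0.10 and 0.08). Of these 538 were above and 317 below zero, and the slope was 0.75. The slopes the other way, of shCTR on sh4, were 0.795 and 0.785, and the call on the repressed set was lost in other settings, among them without any one of 4 arrays.

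The hairpin effects without and with retinoic acid share no array, and across genes they correlated with r = 0.319 and rho = 0.262 (within slides r = 0.285, 0.229 and 0.221). Chance draws of the hairpin labels gave r up to 0.668 in size. These draws ignored the slides, and a draw that follows them can correlate through the slide effect, so they decide nothing on r. For that reason r alone was not taken to show agreement. Of 3020 genes past the threshold in both, 2305, or 76.3%, had the same sign. Both rose for 1154 genes, against 392 for independent lists, both fell for 1151, against 365, and 715 went opposite ways, against 756. With the normexp correction 1309 genes had the same sign in both. The genes alike included Sox7, Gata6, Perp, Btg2 and Phf19, and the trophectoderm list was called only in untreated cells, a difference that the interaction put past the threshold.

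**Figure D4:**
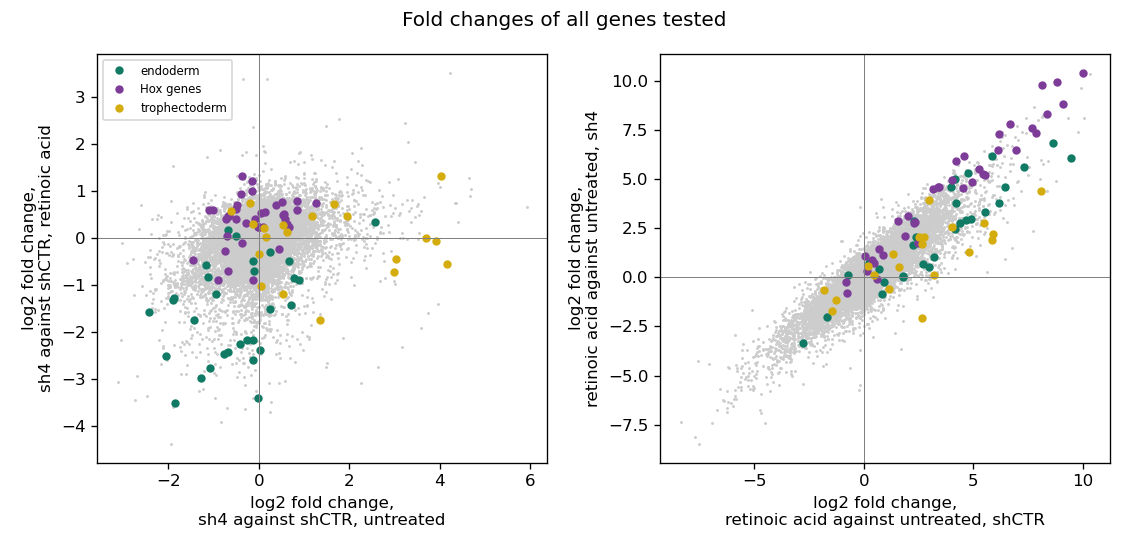
Log2 fold changes of all 25090 genes tested: the hairpin effect in retinoic acid (vertical) against that in untreated cells (horizontal) on the left, and the retinoic acid response of sh4 against that of shCTR on the right; colours mark 3 gene lists. Endoderm genes lie low on the vertical axis of the left plot (median −1.47), and the 2 responses on the right lie near one line (r = 0.903).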

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

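The tests on the endoderm list and on the correlation of the hairpin effects were chosen after the result was seen, and those on the slides and on the other results of regrouping the arrays before. For the number of genes changed, regrouping spoke against a chance labelling of these arrays. It does not test a difference between cultures, and other splits carry the real effect in their spread, which lowers their counts. Of 35 splits only the real one reached its count for sh4 against shCTR untreated (7149, highest other 388, for the split of slides 1 and 2 from slides 3 and 4). It was also alone for sh4 against shCTR in retinoic acid (5308, highest other 880, for 3 of the 4 shCTR arrays against the rest). The same held for retinoic acid in shCTR (15641, highest other 0) and retinoic acid in sh4 (14688, highest other 10430, for a split of 3 of the 4 untreated arrays from the rest). Of the 8 splits of 4 against 4 that part all same-number pairs, those besides the real one gave at most 2 genes for the untreated hairpin and 0 for retinoic acid in shCTR. For the 8 of 3 against 4 that part all same-slide pairs it was 1 for the hairpin in retinoic acid and 9982 for retinoic acid in sh4, where 3 untreated arrays were split from the rest. Of 100 draws of the hairpin labels within each treatment, only the real one reached its count for the interaction (5109 genes, highest other 2998). The same held for the genes alike under both treatments (2305, highest other 1). For the induced set the real value led only narrowly (1 of 100, −0.129, highest other 0.125 in size). These draws ignored the slides, so that a draw that follows them can correlate across treatments through the slide effect. They also removed the hairpin effect within each treatment. They therefore speak only against the absence of any hairpin effect, and test neither a difference between treatments nor an agreement. Chance was not excluded for the repressed set (5 of 100, 0.09, highest other 0.124). Nor was it for the correlation of the hairpin effects without and with retinoic acid (26 of 100, 0.319, highest other 0.668 in size). Nor was it excluded for the number of lists called, where splits with as many numbered 9 of 35 for the hairpin untreated (8 lists, highest other 11), and 2 of 35 in retinoic acid (12, 12). They were 11 of 35 for retinoic acid in shCTR (13, 15), 7 of 35 in sh4 (15, 16) and 21 of 100 for the interaction (8, 14). These counts decide nothing, since the other splits of 35 with as many lists kept most arrays of a group together. For the untreated hairpin and retinoic acid in shCTR, even mixes called at most 1 list. Lists called in the real split, a choice that favours it, had their largest median there for 8 of 8, 8 of 12, 13 of 13 and 14 of 15. Exceptions were retinoic acid targets, endothelial, germ cell and hypoxia genes in retinoic acid, and p53 targets in sh4.

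Arrays of slides 1 and 2 stood apart from those of slides 3 and 4, with 10094 genes past the threshold, 3996 higher and 6098 lower on slides 3 and 4, and Lyar (−4.09), Arhgap19 (−3.88), Cox17 (−3.63) and Aurkb (−3.61) foremost. Single probes that work differently between array lots may account for part of it: for 5097 genes with a second probe the slide effects of both probes correlated at only 0.212, against 0.709 for the hairpin effects. Probe GC content correlated with the slide effect at rho = 0.130, which decides nothing, since a weak trend fits either case. A difference in culture or handling stays open and cannot be told apart from a difference between slides, since 0 of 4 culture lists passed with an estimated correlation and with the preset one the hypoxia list passed, as did primed epiblast, which is not a culture list (adjusted p = 0.035 each; 0.57 and 0.43 with an estimated correlation). No biological explanation was tested, since slides 1 to 3 hold all groups.

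The endoderm list, lower in sh4 than in shCTR after retinoic acid, differed in its hairpin effect between treatments (median −1.66, but −1.37 to −0.96 within slides and −0.68 with the normexp correction, and adjusted p was 0.072 with an estimated correlation). A slide or a scaling did not produce the lower level, whose median stayed at or below −1.31 within each of 3 slides and under 3 other scalings. A response weaker alike in all induced genes is excluded as the whole cause, since it needs a Hox median of −1.73 to −0.97 by slide and scaling and the lowest within slides was 0.385 (spread over genes 0.52, list call lost at 0.094 with an estimated correlation). A weaker response as a part of it stays open, because the induced set had a median interaction of −0.13, with 967 genes lower and 542 higher. A smaller share of endoderm-like cells stays open too and cannot be told apart from a change within cells, since the 17 strong responders, of which 15 fell, had a spread 8.55 times their median standard error but only 2 were near background in untreated shCTR, and differing baselines alone make falls unequal.

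Besides endoderm, the hairpin effect differed between treatments, by the test of the interaction, for Phf19 (0.85), for 5109 genes and for 68 of the 98 genes named for the hairpin, which were chosen in part on the effects compared, so that this share decides nothing. With the preset correlation, trophectoderm (−1.01) and primed epiblast (−0.93) differed too, and both held with an estimated one. Lost with an estimated correlation were naive and core pluripotency (−0.44, adjusted p = 0.44), Hox genes (0.42, 0.14), cyclin-dependent kinase inhibitors (0.38, 0.072), histone genes (0.31, 0.19) and imprinted genes (−0.34, 0.16), and the pluripotency median within slides ran from −0.77 to 0.19. The induced set differed by −0.13. The repressed set, at 0.093, passed with the preset correlation, but not with an estimated one (camera p = 0.17) or without any one of 4 arrays, and regrouping did not exclude chance.

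One array lay far from the other 3 of its group for 23 of 483 groups of 4 tested, where chance gives about 24.2. Among untreated shCTR arrays these log2 levels were, for replicate 1, Aqp8 −1.79, Spink8 −8.86 and Crabp2 0.39, for replicate 3, Sox7 −3.71, Nnat −5.02 and Foxa2 −3.52, and for replicate 4, Slc23a1 −6.21. Among untreated sh4 arrays they were, for replicate 1, H2aw −2.30, Pou5f1 4.07, Epop 4.81 and Cldn8 −9.04, for replicate 2, Plk2 0.25, Pramel7 −3.22, Esam −1.87, H19 0.93 and Il33 −3.72, and for replicate 3, Cdkn2b −4.58 and Cdh22 −4.75. Among treated shCTR arrays they were Stra8 4.94 in replicate 1, Nostrin 1.72 in replicate 2, and H3c8 −0.48, Fabp1 −3.74 and Foxd3 −9.11 in replicate 4.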

How the results depend on the processing

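Only the omission of the 3 arrays rated for evaluation was chosen after the data were seen. With it 5976, 3971, 15364, 13773 and 3885 genes changed for the hairpin untreated and in retinoic acid, retinoic acid in shCTR and in sh4, and the interaction. It ended the calls on H2aw and Zfp42 in untreated cells, on Nanog (−0.89), Zfp42 (−0.63), Hoxc5, Rrm2b and the germ cell list in retinoic acid, and on Hoxd4 in the interaction. Phf19 kept its direction and its call in all 54 values. Counts of genes stayed within 1.5 times in 131 of 139 values. The exceptions were a normexp background correction (4643 for the hairpin untreated, 3389 in retinoic acid, 3050 for the interaction) and the 2-fold minimum (1638, 853, 6963, 6390 and 1478), which is stricter by construction. Normexp also gave 1309 genes alike under both treatments and turned Col3a1 in untreated cells to −0.068. It moved 90 called values of named genes by over 1.5 times, as did the deposited log2 table, and averaging over probes moved 8. Without a filter the correlation of the hairpin effects was r = 0.279. The repressed set lost its call with normexp, replicate number as a block and array weights (camera p of 0.063, 0.065 and 0.082), with medians of 0.12, 0.096 and 0.081 against 0.093, and without single arrays the median ranged from 0.054 to 0.10. Its call was lost without sh4 replicate 4 with retinoic acid, sh4 replicates 1 or 2, or shCTR replicate 3. With camera and an estimated correlation 5 lists were called for the hairpin untreated, 4 in retinoic acid, 9 for retinoic acid in sh4 and 2 for the interaction, and with the slide as a block as well 5, 2, 4 and 2, with 5 of 13 for retinoic acid in shCTR. With fry, which does not compare a list with other genes, they were 22, 21, 26 for retinoic acid in shCTR, 27 and 15. Beyond the constructions named, the cause was not tested. Without single arrays the counts ran from 6328 to 7094, 3936 to 5372, 15063 to 15760, 13814 to 14744 and 4266 to 4941. Of 6973 values of single genes 6903 kept direction and call, and of 2251 values of lists 2173. With only the groups compared, the interaction and the response sets have no value of their own, since they use all groups. Signal over background limits genes near the floor, as Col3a1, Dcn, Cldn8 and Spink8 show with normexp.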

Other observations

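The tests on fibroblasts were chosen after the result was seen, the others here before. Among genes the report did not set side by side, many of those that sh4 raised in untreated cells were also raised by retinoic acid in control cells. Of the 778 genes that rose at least 2-fold in untreated sh4, 592 (76.1%) were raised by retinoic acid in shCTR and 88 lowered. Both rose for 2175 genes, against 1043 for independent lists, and both fell for 1851, against 1184. In opposite directions, 820 genes rose with sh4 and fell with retinoic acid, and 1223 fell with sh4 and rose with retinoic acid. The first count lies below and the second above that for independent lists of these sizes. Genes lowered by sh4 thus also overlapped those raised by retinoic acid. The overlap covers Krt18, which rose by 3.91 with sh4 and 5.86 with retinoic acid, Cxcl10 (2.98 and 8.79), Acta2 (2.96 and 8.21), Peg3 (1.70 and 5.42) and Plk2 (0.99 and 1.68). It does not cover Gata6, a marker of primitive endoderm, which fell by 1.91 with sh4 and rose by 4.75 with retinoic acid, or Tdpoz4, a gene of the 2-cell embryo, at −1.60 and 3.57.

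Both comparisons use the same untreated shCTR arrays, which alone pull their values together: in simulated data without any change, r across genes, which are not independent, was 0.519, so the observed r of 0.251 decides nothing. The covariance was 0.180, against 0.0344 in these simulated data. With the shCTR arrays divided between the comparisons, the covariance kept a median share of 0.880 (0.743 to 0.910), and 68.0% to 75.5% of the genes raised at least 2-fold were raised by retinoic acid, so the shared arrays are not the whole source. The gain or loss of a whole chromosome in most cells does not account for it, as the largest median of any chromosome was 0.0870 in size, on X. In untreated cells 22.5% of the genes on X rose and 10.8% fell (camera adjusted p = 0.31), against at most 17.6% that rose on an autosome. A change of X in a part of the cells was not tested. Fibroblasts among the untreated sh4 cells stay open. Their list had a median of 0.11, or −0.07 under another scaling, with a spread over genes of 1.25. With 11 of 23 members up and 7 down, the list decides nothing. Acta2 measured 2.96 and Tagln 1.94, while Thy1 measured −1.71 and Fbln2 −0.98. Of the list's abundant collagens Col1a1 measured −0.51 and Col1a2 0.11. With retinoic acid in shCTR 20 of the 23 rose, but total RNA does not tell whether ES-derived cells or fibroblasts in the culture expressed them. As a hypothesis, untreated sh4 cells may hold part of the expression state that retinoic acid brings about. The genes that fell with sh4 and rose with retinoic acid lie outside it. The hypothesis cannot be told apart from fibroblasts for the genes that fibroblasts express. Whether low Phf19 or another effect of 1 hairpin lies behind the overlap was not tested.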
